A study of Mus musculus with 6 samples.

How the data were processed

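Messenger RNA levels were measured by RNA-seq in mouse primordial germ cell-like cells (PGCLCs), which are made in culture from embryonic stem cells by way of an epiblast-like state and model the first days of the germ line. Per the labels' protocols, the stem cell line was C57BL/6, carried floxed Ezh2 alleles and a Cre recombinase that 4-hydroxytamoxifen activates, and was aggregated in medium with BMP2, SCF, LIF and EGF. The 3 Ezh2 KO libraries came from aggregates given 4-hydroxytamoxifen in ethanol and the 3 Ctrl libraries from aggregates given ethanol alone, all taken on day 4. Cells were dissociated and sorted before RNA extraction, and libraries were made with a kit for low RNA input, per the labels' protocols. The sorting gate, the exons between the loxP sites and the sex of the line are not given in the sources used here. No label says whether the replicates came from separate inductions, so p-values measure the spread between these samples, part of which may be technical.

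The authors deposited 1 table of whole-number read counts per Ensembl gene, not normalized, with a column for each of the 6 libraries. CASAVA 1.8.4, Trimmomatic 0.33, TopHat2 2.0.11 and featureCounts are named, with the builds mm9 and NCBIM37, per the submitters' processing notes; their settings, the use of strand and the version of the annotation are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense partner cannot be told apart in these counts, and near-identical copies such as the Zscan4, Rhox and Ifitm families are uncertain because their reads can be shared. The table held 37991 gene IDs, of which 11017 had no count in any library. Symbols, chromosomes and transcript GC content came from GENCODE M21, matched by gene ID: 32919 IDs had a symbol and 5072 did not, and the latter held 1.80% to 2.73% of the counts of a library. Because that annotation belongs to another build than the authors', no coordinates are printed.

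Total counts per library ran from 27072150 to 49382146. The genes kept by filterByExpr with its defaults (minimum count 10) numbered 16420, and the other 21571 were not tested. Counts were scaled by TMM factors and tested with the quasi-likelihood F-test of edgeR 4.0.16 under R 4.3.3, in its robust form with group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM, read counts scaled by edgeR to a common library size after TMM, given as mean ± SD over 3 libraries. Log2 fold changes are Ezh2 KO over Ctrl, with the standard error derived from the F statistic and 95% intervals on the same degrees of freedom. Principal components were computed on log2 CPM with a prior count of 2.

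The 27 gene lists held 605 entries written before the data were examined, of which 593 matched a gene ID. They cover PRC2 and PRC1, germ cell and pluripotency genes, Hox and lineage genes, markers of other cells that aggregates can hold, imprinted genes, stress responses and the cell cycle. Each list was compared with all other tested genes by camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 27 lists. Autosomes and the X chromosome were tested in the same way as a separate family of 20 lists. Members were also adjusted over the list alone.

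The genes named were to be 11 fixed ones (Ezh2, Ezh1, Eed, Suz12, Prdm1, Prdm14, Tfap2c, Dppa3, Nanos3, Dazl and Ddx4). To these came up to 6 of the largest rises and 6 of the largest falls among changed genes of mean log2 CPM of at least 1 whose libraries do not overlap, and up to 2 changed members of each list. As 0 genes met the last parts of this rule, further genes were chosen after their values were seen. They are the 2 members of smallest p in each list that camera called, list members past 0.05 adjusted over the list alone, the genes called by DESeq2, and the largest changes by the same rule among the calls of DESeq2 with the replicate block. Mdm2 and Cdkn2a, members of the p53 and CDK inhibitor lists, were singled out beside these, also after their values were seen.

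Alternatives chosen before the data were examined were size factors of DESeq2 in edgeR, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (CPM of at least 1 in 3 libraries and a mean of 20 counts), the replicate number as a block, each library left out in turn, thresholds of 0.01 and 0.10, a test against a 2-fold change, camera with an estimated correlation, and fry. Chosen after seeing the data were DESeq2 with the block, DESeq2 with its filtering set for 0.05, an offset for GC content in each library (loess, span 0.5) with and without the block, voom with library weights, removal of the 2 libraries at the ends of the first principal component, and the estimated correlation with the block. The GC offset was fitted on genes of mean log2 CPM over 2 and applied to all tested genes.

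Replicate numbers 1 to 3 occur in both groups. Deviations from the group means correlated between same-numbered libraries at 0.58, 0.37 and 0.19 for replicates 1, 2 and 3 across genes, each above the limit of 0.1 set beforehand, and at 0.50, 0.33 and 0.26 after the GC offset. Of the 6 pairs of other numbers, Ctrl replicate 3 with Ezh2 KO replicate 2 correlated at 0.30, above the value of the replicate 3 pair, and the others between -0.52 and -0.02. The numbers were therefore taken to pair the samples, a pairing that rests on the data and on shared numbers and not on a stated shared induction. The main fit was set beforehand without this pairing. Its standard errors, intervals and p-values therefore also hold the spread between pairs, and blocked values are named as such. Deviations from a mean cancel within a group, so some pairs must correlate positively, and the limit cannot establish the pairing. No 2 libraries were alike within sampling noise: the chi-square per degree of freedom was 29.7 to 152 within groups.

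The tests were tried on simulated data. In counts drawn from the real means of the 16420 genes, edgeR without a block recovered 31.3%, 76.1% and 89.4% of genes altered 2-, 4- and 8-fold, with 18 calls among unaltered genes, and with the block 13.4%, 68.7% and 86.4%, with 6 such calls. In the real counts thinned by known folds it recovered 19.4%, 62.7% and 90.9%, with 1 call among unaltered genes, and with the block 43.3%, 88.1% and 97.0%, with 29 such calls. The thinned counts kept the real groups, so calls among their unaltered genes can include real differences and are not a count of errors. DESeq2 made 56 calls among unaltered genes in the drawn counts and 62 in the thinned counts without the block, and 67 and 95 with it. It recovered more of the altered genes than edgeR did: without the block, 43.3% of those altered 2-fold in the drawn counts and 65.7% in the thinned counts. Camera gave the shifted list an adjusted p of 5.5e-17 and a p under 0.05 to 1 of 200 unaltered lists of 20 genes. These genes were drawn independently, so the trial does not check the preset correlation for lists whose members vary together. In the real data the estimated correlation of the 11 lists that camera called ran from -0.03 (imprinted through H3K27me3) to 0.86 (2-cell-like). With an estimated correlation camera also rests on the few residual degrees of freedom of these libraries, so its power was low. A call lost in that setting need not come from members that vary together.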

Results

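RNA-seq read counts were analysed for mouse PGCLCs on day 4 of induction, with 3 control libraries (Ctrl) and 3 libraries from cells in which deletion of floxed Ezh2 had been induced (Ezh2 KO). Ezh2 is the main methyltransferase of polycomb repressive complex 2 (PRC2), which places the repressive mark H3K27me3. The comparison asks which transcripts of early germ cells depend on that enzyme. Total counts were 49382146, 27358959 and 28464845 in Ctrl replicates 1 to 3 and 37814692, 27072150 and 38643944 in Ezh2 KO replicates 1 to 3. Mitochondrially encoded genes held 1.79%, 2.47% and 3.02% of the counts in Ctrl and 1.90%, 3.37% and 2.92% in Ezh2 KO. The 10 most abundant genes held 5.76% to 7.87% of a library.

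Ezh2 transcripts (ENSMUSG00000029687) were less abundant in each Ezh2 KO library than in any Ctrl library, but were far from absent. The level was 88.4 ± 9.09 CPM in Ctrl (SD, n = 3) and 59.3 ± 16.1 CPM in Ezh2 KO (SD, n = 3), or 67.1% of Ctrl with a 95% interval of 46.5% to 96.7%. Ctrl replicates 1 to 3 held 91.8, 78.1 and 95.3 CPM, and Ezh2 KO replicates 1 to 3 held 40.8, 67.1 and 70.0 CPM, which is 44.4%, 85.9% and 73.5% of the Ctrl library of the same number. The difference in Ezh2 did not pass edgeR's quasi-likelihood test after adjustment (log2 fold change -0.58 ± 0.23 SE, unadjusted p = 0.0361, adjusted p = 0.976). An exact two-sided permutation test on the CPM gave p = 0.1, the smallest that 3 libraries against 3 allow. Without Ezh2 KO replicate 1 the log2 fold change of Ezh2 was -0.37. Counts over the whole gene keep reads from exons outside the deleted part, so these values do not measure how much functional Ezh2 was left.

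**Figure D1:**
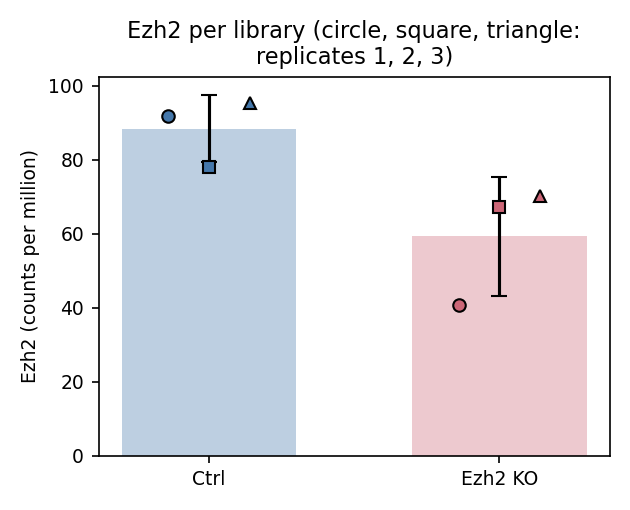
Ezh2 level in CPM (vertical axis) in the 3 Ctrl and 3 Ezh2 KO libraries; bars are group means, error bars SD, and symbols single libraries. The Ezh2 KO libraries lie at 40.8 to 70.0 CPM, all below the Ctrl libraries at 78.1 to 95.3 CPM.

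Of the other PRC2 genes, 0 passed the edgeR test. Eed, which binds the methyl mark, stood at 252 ± 36.6 CPM in Ctrl and 258 ± 43.4 CPM in Ezh2 KO (log2 fold change 0.03, 95% interval -0.36 to 0.43). Suz12, the scaffold subunit, stood at 178 ± 65.9 and 180 ± 64.6 CPM (0.02, -0.80 to 0.83). With the replicate block the SE of the log2 fold change of Suz12 was 0.15, against 0.35 without it. Ezh1, the paralog of Ezh2, stood at 42.2 ± 8.45 and 33.5 ± 18.3 CPM (-0.33, -1.21 to 0.55). Over the 12 PRC2 genes the median log2 fold change was -0.05 and over 19 tested PRC1 genes -0.06, and neither list passed camera (adjusted p = 0.120 for both). Without Ctrl replicate 1 the PRC2 list passed as lower (adjusted p = 0.0291, range 0.0291 to 0.418 over the alternatives), and without Ezh2 KO replicate 3 the PRC1 list did (0.0435, range 0.0435 to 0.890).

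At the level of single genes, the transcripts that DESeq2 called were few and of low abundance. The homeobox gene Hoxa7, which patterns the body axis, was at 3.17 ± 0.329 CPM in Ctrl and 0.838 ± 0.0713 CPM in Ezh2 KO (log2 fold change -1.91 ± 0.30 SE). Msx1, a homeobox target of BMP signalling, was at 3.42 ± 3.12 and 0.332 ± 0.0782 CPM (-3.36 ± 0.76), with 6.88 CPM in Ctrl replicate 2. In the other direction lay Ptgs1, which encodes cyclooxygenase 1, at 0.385 ± 0.0911 and 1.87 ± 0.637 CPM (2.27 ± 0.41), Krtdap, a keratinocyte differentiation gene, at 2.30 ± 0.790 and 7.36 ± 1.75 CPM (1.68 ± 0.35), and Serping1, the C1 inhibitor of complement, at 6.99 ± 0.671 and 13.5 ± 0.443 CPM (0.95 ± 0.22). These 5 genes, each with all Ezh2 KO libraries on one side of all Ctrl libraries, were the calls (adjusted p = 2.90e-05 for Hoxa7, 0.0127 for Msx1, Ptgs1 and Krtdap, and 0.0237 for Serping1). Such a lack of overlap was seen in 8.09% of all tested genes, where chance gives 10%. Of the 10 splits of the libraries 3 against 3, 6 gave as many calls of this fit or more, the real split included, with 734 at most. In drawn counts this fit made 56 calls among unaltered genes. With the replicate block Serping1 was not called by DESeq2 (adjusted p = 0.0558).

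The quasi-likelihood test of edgeR called 0 of 16420 genes, and limma-voom 0 as well. The smallest edgeR adjusted p was 0.976, and 459 genes had an unadjusted p under 0.05 (254 higher and 205 lower in Ezh2 KO) where chance gives 821. Limma-voom had 466 genes at an unadjusted p under 0.05 and DESeq2 737, where chance gives 1349 for the genes that DESeq2 tested, and leaving out Ezh2 KO replicate 1 gave 1432 in edgeR, with 0 called. The 3 libraries of a group did not overlap with those of the other group in 1329 genes (8.09%, 668 higher and 661 lower), and chance gives 10%. Without the replicate block, and so with the spread between pairs left in, the biological coefficient of variation was 30.6%. In that fit the median half-width of a gene's 95% interval was 0.71 on the log2 scale. It was 0.44 for the 5354 genes of mean log2 CPM over 5. With the replicate number as a block the coefficient was 22.7%, edgeR again called 0 genes (smallest adjusted p 0.158), and 1495 had an unadjusted p under 0.05 (982 higher and 513 lower).

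DESeq2 with the replicate block called 50 genes, 23 higher and 27 lower, and 45 of them by at least 2-fold. Of the 50, 43 were also tested by edgeR. In drawn counts with 200 altered genes, the same fit made 67 calls among unaltered genes, so single calls of this fit are uncertain. The drawn counts held no pair effect, and their altered genes loosen the adjusted threshold, so the 67 cannot be set against the 50. Thinned real counts gave 95 such calls, but they kept the real groups, so these calls can include real differences. Of the 4 splits of the libraries that part the 3 pairs, those other than the real one gave at most 2 calls. As few as 4 splits cannot serve as a test. Among the higher genes were Sfmbt2, a polycomb group gene, at 51.6 ± 13.6 CPM in Ctrl and 113 ± 22.9 CPM in Ezh2 KO (blocked log2 fold change 1.13, adjusted p = 7.08e-04), and Ptges, which makes prostaglandin E2, at 7.40 ± 1.54 and 16.7 ± 2.99 CPM (1.17, adjusted p = 0.00289). Map1a, a microtubule-binding protein gene, had a blocked log2 fold change of 1.40 (adjusted p = 6.07e-04), and Ddah1, which degrades an inhibitor of nitric oxide synthesis, one of 1.13 (adjusted p = 0.00697). Irgm1 (1.39, adjusted p = 0.0296) and Xaf1 (1.20, adjusted p = 0.00697) were higher too. Tmem121 (-1.35, adjusted p = 0.0324) and Mobp (-1.02, adjusted p = 0.0393) were lower. The most abundant gene named was Slc2a3, which encodes a neuronal-type glucose transporter and was lower, at 5098 ± 1065 CPM in Ctrl and 2498 ± 589.5 CPM in Ezh2 KO (-1.05, adjusted p = 0.0344). Dlk1, a paternally expressed imprinted gene, was lower as well (-2.41, adjusted p = 2.76e-04), though its Ctrl level of 6.39 ± 6.36 CPM rested largely on Ctrl replicate 2, at 13.5 CPM. In edgeR with the block all 43 had an unadjusted p under 0.05 and adjusted p of 0.158 to 0.466.

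**Figure D2:**
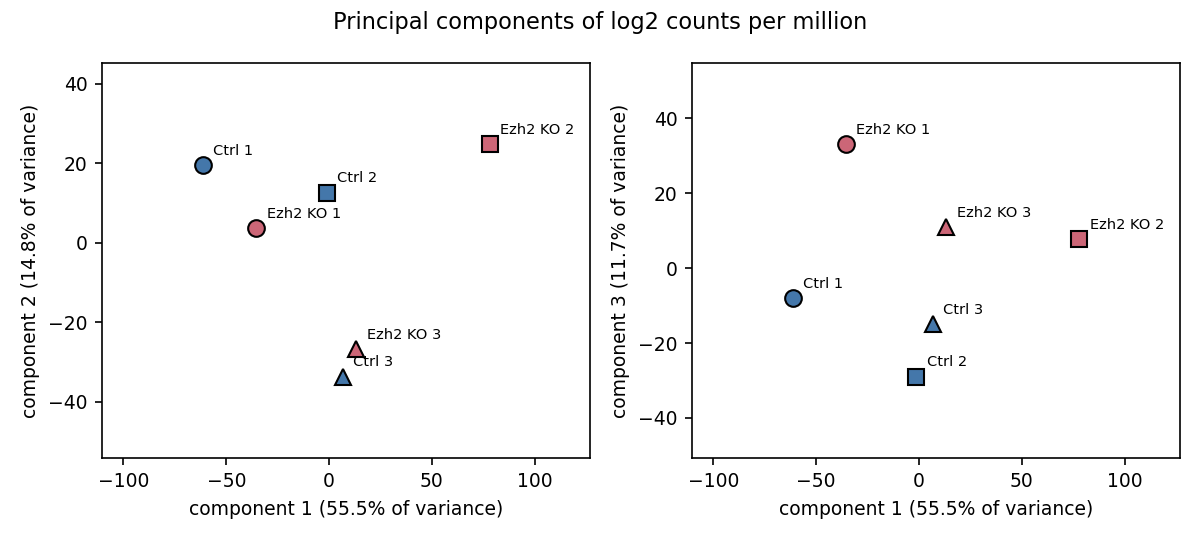
Position of the 6 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM; blue is Ctrl, red Ezh2 KO, and circles, squares and triangles are replicates 1, 2 and 3. The groups part on component 3, with 11.7% of the variance, and not on component 1, with 55.5%.

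Libraries of one group lay far apart on the main axis of variation. The first principal component held 55.5% of the variance and placed Ctrl replicate 1 (-61.4) and Ezh2 KO replicate 2 (78.0) at its ends, with the others between -35.5 and 13.3; its loadings correlated with transcript GC content across genes (Spearman's rho -0.52; genes are not independent replicates). The third component, with 11.7%, had the Ctrl libraries between -28.9 and -7.99 and the Ezh2 KO libraries between 7.74 and 33.1. Chance parts 3 libraries from 3 on a given component in 10% of cases. That parting was not tested and does not establish a group axis. Spearman correlations between libraries were 0.950 to 0.987 within groups and 0.969 to 0.990 between same-numbered libraries of the 2 groups.

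Among the gene lists, Hox genes and markers of the somatic lineages were lower as groups in Ezh2 KO at the preset correlation of camera. With an estimated correlation none of these calls was reached (adjusted p = 0.143 for Hox and for neuroectoderm, 0.188 for mesoderm and 0.477 for endoderm). That setting also rests on few residual degrees of freedom. The unadjusted camera p of the mesoderm list rose from 0.00237 to 0.0284 although its estimated correlation, -0.01, was below the preset one. Of 38 Hox genes found, 9 were abundant enough to test, and 8 of these had a negative log2 fold change, with a median of -1.34. No Hox gene passed edgeR over all genes. Adjusted over the list alone, 3 were lower in edgeR, among them Hoxa7 (adjusted p = 0.00190) and its cluster neighbour Hoxa9 (-2.58 ± 0.55 SE, adjusted p = 0.00623), and 5 were with the block. The summed Hox level was 19.8, 20.3 and 11.7 CPM in the Ctrl libraries and 7.22, 6.02 and 6.82 CPM in the Ezh2 KO libraries. Camera called the Hox list at the preset correlation with an adjusted p of 1.14e-10 (adjusted p = 0.143 with an estimated correlation).

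Neuroectoderm genes, of which 16 of 50 found were tested, had a median log2 fold change of -0.45, and 14 of the 16 were negative (camera adjusted p = 1.72e-06; adjusted p = 0.143 with an estimated correlation). Adjusted over the list alone, 2 were lower in edgeR (adjusted p = 0.0267 for both), and 4 were with the block. The 2 were the proneural factor Neurog1, at 1.35 ± 0.405 CPM in Ctrl and 0.251 ± 0.190 CPM in Ezh2 KO, and Lhx2, a forebrain and eye regulator, at 0.351 ± 0.0406 and 0.0729 ± 0.0372 CPM. Lhx2 was near the limit of detection, with 0.309 to 0.390 CPM in the Ctrl libraries and 0.0494 to 0.116 CPM in the Ezh2 KO libraries. Mesoderm and primitive streak genes (23 tested, median -0.37, 16 negative) were lower as a group too (adjusted p = 0.00914; adjusted p = 0.188 with an estimated correlation), with Msx1 and Cdx2 at the front, and the call ended under the stricter filter (0.234) and in limma-voom (0.0508), with a range of 4.31e-07 to 0.234. Cdx2, which specifies posterior, gut and trophoblast fate and is in those 3 lists, was at 0.851 ± 0.186 and 0.375 ± 0.122 CPM. Endoderm genes (15 tested, median -0.31) had an adjusted p of 0.00929, against an adjusted p of 0.477 with an estimated correlation; Foxa3, a hepatic and gut factor, was at 1.57 ± 1.02 and 0.589 ± 0.296 CPM. That call was lost without Ctrl replicate 1 (0.125), Ctrl replicate 3 (0.104) or Ezh2 KO replicate 2 (0.234), with a range of 0.00385 to 0.623. It was also lost in DESeq2 with the replicate block (0.0563, against 0.0297 without it), and the summed level of the endoderm list was not lower (48.1 ± 4.68 and 48.9 ± 16.3 CPM). In the mesoderm and endoderm lists 0 members passed over the list alone, and with the block 2 mesoderm genes were lower and 0 endoderm genes passed.

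Markers of other cell types that aggregates or sorted cells can hold went partly the same way. Fibroblast and matrix genes (15 tested, median -0.26) had an adjusted p of 0.0448, with an adjusted p of 0.651 with an estimated correlation and 0.0633 with the replicate block, so this call was not kept under pairing; it also ended without Ctrl replicate 1 (0.768) or Ezh2 KO replicate 2 (0.452), with a range of 0.0105 to 0.768. Within it the collagen gene Col5a1 was at 0.930 ± 0.247 CPM in Ctrl and 0.412 ± 0.0908 CPM in Ezh2 KO, and Ccn1, a secreted matrix protein gene, at 38.3 ± 4.34 and 67.2 ± 18.4 CPM, and 0 members passed over the list alone, or 1, higher, with the block. Trophoblast genes (18 tested, median -0.10, adjusted p = 0.354) did not pass. Blood and endothelium genes (13 tested, adjusted p = 0.977) did not either; their median was -0.17, their mean 0.12 and the direction of the test lower.

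**Figure D3:**
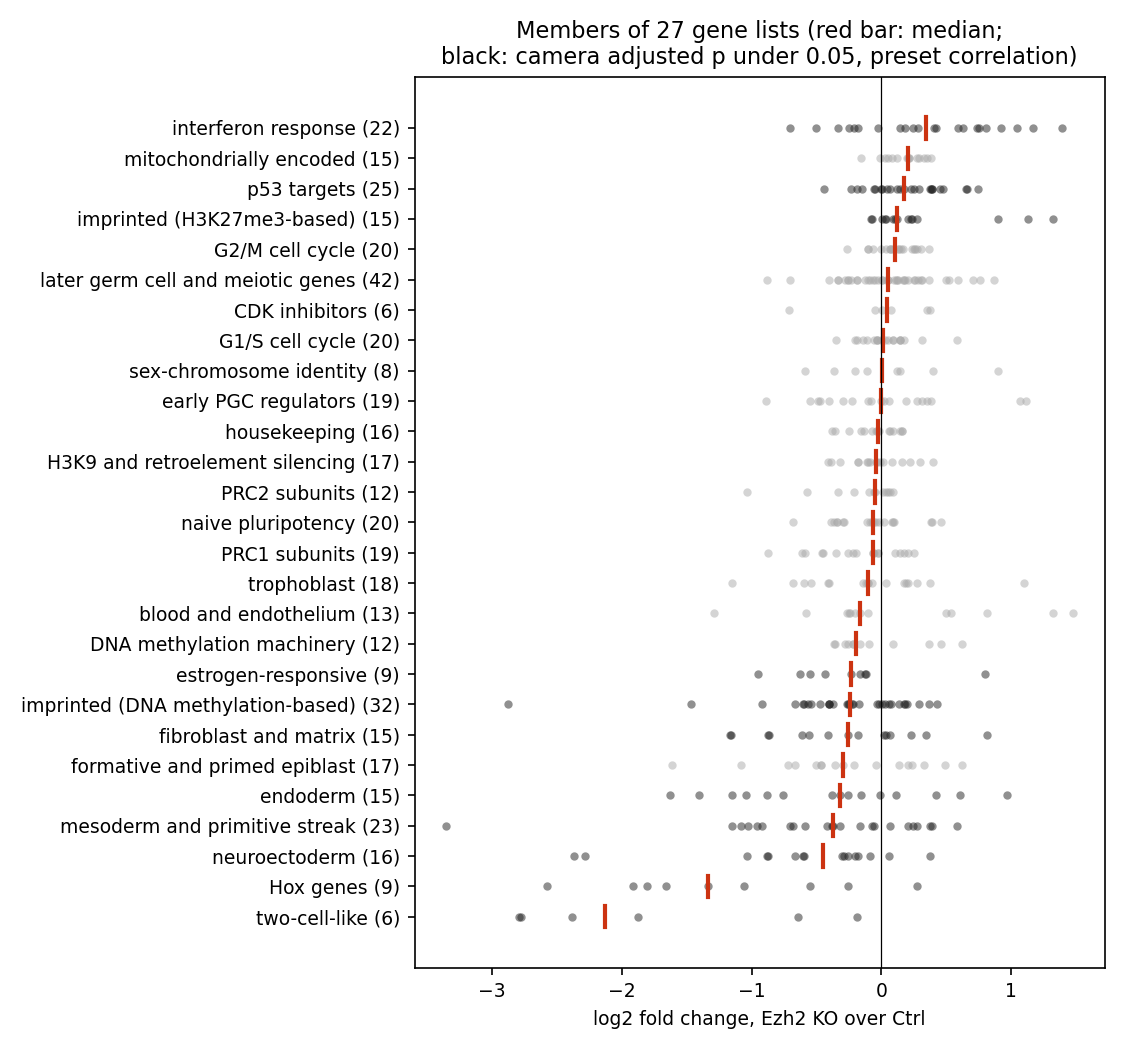
Log2 fold changes (horizontal axis, Ezh2 KO over Ctrl) of the tested members of the 27 gene lists, with the number tested in brackets; red bars are list medians, and black points mark the 11 lists that camera called at the preset correlation. The Hox list has its median at -1.34 and the interferon list at 0.35.

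Genes of the interferon response and targets of p53 were higher as groups at the preset correlation of camera, and neither list passed with an estimated correlation (adjusted p = 0.356 and 0.188). Of 22 interferon genes tested, 15 had a positive log2 fold change, with a median of 0.35, and 7 had an unadjusted p under 0.05, all higher. Oas2, an antiviral RNA sensor, was at 1.31 ± 0.398 CPM in Ctrl and 3.45 ± 1.01 CPM in Ezh2 KO (1.39 ± 0.38 SE). The list had an adjusted p of 5.04e-04 (0.356 with an estimated correlation); 0 members passed over the list alone, and 2 did with the block. Of 25 p53 targets, 18 were positive, with a median of 0.18, among them Perp at 44.4 ± 7.36 and 70.2 ± 8.57 CPM and Plk2 at 52.6 ± 17.0 and 88.2 ± 13.4 CPM. The p53 list had an adjusted p of 0.00454 (0.188 with an estimated correlation), with 0 members past the threshold over the list alone and 1 with the block. Summed over the list, p53 targets stood at 2724 ± 88.3 CPM in Ctrl and 3112 ± 189 CPM in Ezh2 KO, while Mdm2, the feedback inhibitor of p53, was at 239 ± 15.2 and 239.7 ± 0.180 CPM. The 6 CDK inhibitors, which include the polycomb target Cdkn2a at 2.28 ± 0.367 and 2.91 ± 1.36 CPM, did not pass (adjusted p = 0.934).

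**Figure D4:**
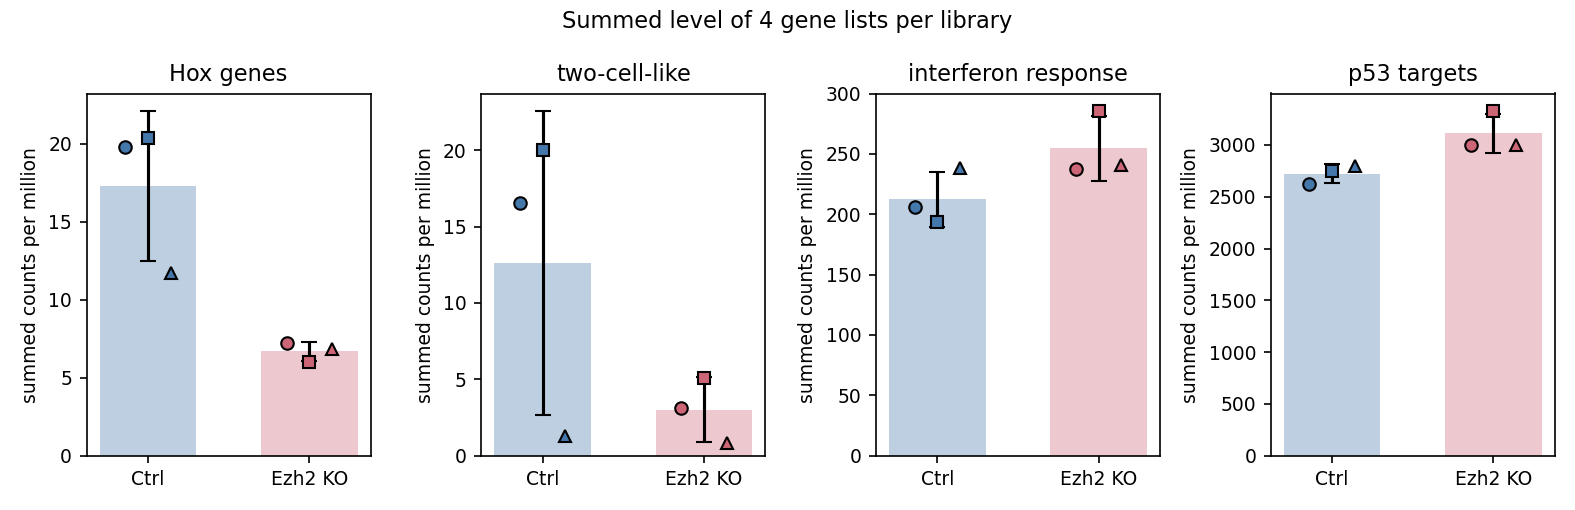
Summed levels in CPM (vertical axes) of the matched members of 4 lists in each library; bars are group means, error bars SD, and circles, squares and triangles replicates 1, 2 and 3. Hox sums in Ezh2 KO lie at 6.02 to 7.22 CPM against 11.7 to 20.3 CPM in Ctrl, and the 2-cell-like sums of the replicate 3 libraries lie at 1.31 CPM in Ctrl and 0.815 CPM in Ezh2 KO.

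Imprinted genes were tested as 2 lists by the kind of imprint, and the lists were not tested against each other. Genes imprinted through DNA methylation (32 tested, 21 negative, median -0.24) were lower as a group (adjusted p = 0.00138; adjusted p = 0.143 with an estimated correlation), with Dlk1 and Magel2 (0.867 ± 0.218 CPM in Ctrl and 0.308 ± 0.0135 CPM in Ezh2 KO) at the front; without Ezh2 KO replicate 1 the adjusted p was 0.0938, the highest of a range from 9.34e-07, and 0 members passed over the list alone, or 1, lower, with the block. Genes imprinted through H3K27me3 (15 tested, 13 positive, median 0.12) were higher as a group (adjusted p = 0.0169; adjusted p = 0.188 with an estimated correlation). Sfmbt2 was the 1 member higher over the list alone in edgeR (adjusted p = 0.0270), and Runx1, next by p, was near the limit of detection at 0.210 ± 0.141 and 0.521 ± 0.307 CPM. The second call was lost without Ctrl replicate 2 (0.150), Ezh2 KO replicate 1 (0.0699) or Ezh2 KO replicate 3 (0.0865), with a range of 0.00205 to 0.150. It was also lost under the GC offset with the replicate block (0.0604, against 0.0391 under the offset alone).

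Genes of the 2-cell-like state, a transient state of stem cells marked by the Zscan4 cluster, were lower in Ezh2 KO (6 tested, all 6 negative, median -2.13, adjusted p = 0.00256; adjusted p = 0.477 with an estimated correlation). Their summed level was 16.6, 20.0 and 1.31 CPM in Ctrl replicates 1 to 3 and 3.10, 5.10 and 0.815 CPM in Ezh2 KO replicates 1 to 3. Zscan4f itself was at 4.40 ± 3.76 and 0.658 ± 0.622 CPM; the copies of this cluster are nearly identical, so their separate values are uncertain. Over the list alone 0 members passed, and 4 were lower with the block. Without Ctrl replicate 2 the list no longer passed (0.143, range 1.05e-14 to 0.143). Estrogen-responsive genes, a control for the action of the tamoxifen compound, had 8 of 9 negative with a median of -0.24 (adjusted p = 0.0448; adjusted p = 0.271 with an estimated correlation), led by Myb at 5.54 ± 1.81 and 2.87 ± 0.991 CPM, with 0 members past the threshold over the list alone and 1, lower, with the block. That call was lost without Ctrl replicates 1 (0.101) or 2 (0.150), or without Ezh2 KO replicates 1 (0.168), 2 (0.0739) or 3 (0.0531), with a range of 0.0212 to 0.319.

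Regulators of germ cell fate did not pass as a group. The early PGC list (19 tested) had a median log2 fold change of -0.0026, a mean of 0.01 and a camera direction of lower (adjusted p = 0.970). Prdm1 was at 5.96 ± 1.23 CPM in Ctrl and 4.30 ± 1.31 CPM in Ezh2 KO (log2 fold change -0.47, 95% interval -1.21 to 0.26), Prdm14 at 55.5 ± 9.16 and 56.4 ± 13.1 CPM (0.02, -0.48 to 0.53), and Tfap2c at 300.2 ± 20.1 and 227 ± 73.0 CPM (-0.41, -0.96 to 0.14). Dppa3, which protects imprints in the zygote, was at 222 ± 28.6 and 181 ± 52.5 CPM (-0.29, -0.79 to 0.21), and Nanos3, which germ cells need to survive, at 8.99 ± 3.66 and 10.9 ± 4.39 CPM (0.28, -0.66 to 1.21). Within the list 3 members passed edgeR when adjusted over the list alone (adjusted p = 0.0336 for each). The X-linked homeobox genes Rhox6 and Rhox9 were higher, at 61.4 ± 22.6 and 133 ± 33.0 CPM and at 52.8 ± 18.6 and 111 ± 25.4 CPM, and Ifitm1, a membrane protein gene of nascent germ cells, was lower, at 428 ± 25.8 and 231 ± 66.9 CPM.

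Later germ cell and meiotic genes (42 tested, median 0.05, adjusted p = 0.707) did not pass, and passed without Ezh2 KO replicate 3 (0.0435, range 0.0435 to 0.956). Dazl stood at 44.8 ± 8.51 and 48.5 ± 13.6 CPM (0.12, 95% interval -0.49 to 0.72) and Ddx4 at 21.5 ± 2.71 and 22.0 ± 6.53 CPM (0.03, -0.57 to 0.63). Naive pluripotency genes (20 tested, median -0.06, adjusted p = 0.424) did not pass. Formative and primed epiblast genes (17 tested, median -0.30, adjusted p = 0.185) did not either, and did without Ctrl replicate 3 (0.0373, range 0.0373 to 0.768); 0 members passed over the list alone, and 1 was lower with the block.

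The remaining lists did not pass camera. Adjusted p was 0.707 for the DNA methylation machinery, 0.576 for silencers that act through H3K9 and on retroelements, 0.593 for housekeeping genes, 0.779 for G1/S genes and 0.934 for genes of sex-chromosome identity, whose median (0.01) and mean (0.04) were positive while the test pointed lower. G2/M genes (median 0.11) and mitochondrially encoded genes (median 0.21) each had an adjusted p of 0.120. The G2/M list passed without Ctrl replicate 1 (0.0291) or Ezh2 KO replicate 3 (0.0154, range 0.0154 to 0.630), and the mitochondrial list without Ctrl replicate 3 (0.00365) or Ezh2 KO replicate 1 (4.08e-04, range 4.08e-04 to 0.910). In all, 11 of the 27 lists passed at the preset correlation, 3 higher and 8 lower, and 0 passed with an estimated correlation; 9 members passed over the list alone, 3 higher and 6 lower, against 0 over all genes, and 26 passed over the list alone with the replicate block.

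Polycomb marks the inactive X chromosome of female cells, so X-linked genes were tested as one list. The 770 X-linked genes had a median log2 fold change of 0.09 and did not pass (camera adjusted p = 0.308; adjusted p = 0.813 with an estimated correlation), and none of the 19 autosomes passed (smallest adjusted p 0.222, chromosome 7). Without Ezh2 KO replicate 1 the X-linked genes passed as higher (0.0226), and the direction was lower without Ctrl replicate 1 (0.995) or Ezh2 KO replicate 2 (0.863).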

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

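Added after seeing the data were the DESeq2 fits with the block and with filtering set for 0.05, the GC offsets, voom with library weights, removal of the 2 libraries at the ends of the first component, and the estimated correlation with the block. EdgeR and limma-voom called 0 genes under each alternative run, thresholds of 0.01 and 0.10 and each library left out included. DESeq2 called 5 genes (3 higher, 2 lower, 4 of them 2-fold), 13 with filtering set for 0.05 (8 higher, 5 lower, 12 of them 2-fold) and 50 with the replicate block (23 higher, 27 lower, 45 of them 2-fold); 4 of the 5, all but Serping1, were among the 50. The cause of the gap between tools was not tested, but in counts drawn from the real means DESeq2 recovered more altered genes. It also made more calls among unaltered genes there. Of the 11 lists called, 7 passed under the stricter filter, which tests fewer genes, 0 with an estimated correlation, 0 with an estimated correlation and the replicate block, 0 in fry (smallest adjusted p 0.135) and 4 in fry for either direction (Hox, neuroectoderm, interferon and fibroblast). With a library left out, 8 to 12 of the 27 lists passed.

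Hox, neuroectoderm, interferon and p53 lists passed in all 18 alternatives at the preset correlation, with adjusted p up to 2.47e-04, 0.0130, 0.0306 and 0.0483. Without the 2 libraries at the ends of the first component, the direction turned for 3 results that passed in either setting: X-linked genes came out lower (adjusted p = 0.0189), mitochondrially encoded genes lower (0.0130) and fibroblast genes higher, uncalled (0.532). The adjusted p of X-linked genes ran from 0.0226 to 0.995 over the libraries left out, with the direction turned without Ctrl replicate 1 or Ezh2 KO replicate 2 and under voom with library weights (0.996); the cause was not tested. The log2 fold change of Ezh2 ran from -0.71 to -0.37 and was called in no setting. Sex-chromosome genes passed as lower without the 2 libraries (0.00197), and 2-cell-like genes had no value under the stricter filter. In all, 506 values of lists kept their side of the threshold, 76 lost a call and 9 gained one, and of gene values 822 kept theirs and 31 gained a call. In the edgeR fit the replicate block ended the fibroblast call (0.0633) and changed no other list call of camera at the preset correlation, so that 10 lists passed, all among the 11. In DESeq2 the block ended the endoderm call (0.0563, against 0.0297 without it) and no other. Under the GC offset it ended the call of genes imprinted through H3K27me3 (0.0604, against 0.0391), and estrogen-responsive genes passed only with it (0.0376, against 0.0505). The block changed no edgeR call over all genes, which stayed at 0, but over the list alone 26 members passed with it against 9 without. DESeq2 with the block and a GC offset called 74 genes, 40 of them among the 43 of the 50 that it tested. Some lists were tested only in part: of 38 Hox genes found, 29 were too low to test.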

Other observations

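The splits of the libraries were set before their counts were seen, but those of DESeq2 with the replicate block use a fit added after the data were seen. The other tests of explanations in this part, and the sums over list members, were chosen after the result was seen. Lineage genes too low to test one by one were summed per library. The 29 untested Hox genes together held 2.63 ± 1.35 CPM in Ctrl and 0.587 ± 0.279 CPM in Ezh2 KO (SD, n = 3). The 34 untested neuroectoderm genes held 2.23 ± 0.400 and 1.03 ± 0.0885 CPM, and the 21 untested mesoderm and primitive streak genes 2.95 ± 0.626 and 1.27 ± 0.144 CPM. The 9 untested endoderm genes held 1.24 ± 0.569 and 0.980 ± 0.260 CPM. Summed over all members found, neuroectoderm genes held 112 ± 24.6 and 104 ± 28.3 CPM and mesoderm and primitive streak genes 115 ± 14.5 and 101 ± 20.4 CPM; Hox genes held 17.3 ± 4.83 and 6.69 ± 0.609 CPM. By pair, the neuroectoderm sums were 87.6 and 133, 137 and 76.8, and 110.5 and 102 CPM (Ctrl and Ezh2 KO replicates 1 to 3), which go both ways. The mesoderm sums were 112 and 86.8, 101.5 and 92.3, and 130 and 125 CPM, with the Ezh2 KO library below its Ctrl library in all 3 pairs; these sums were not tested.

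The lower Hox level stands out, since loss of PRC2 is known to release Hox genes in many cells. The median log2 fold change of the 9 tested Hox genes was -1.34 before the GC offset and -1.34 after it. That offset was fitted on genes of mean log2 CPM over 2, and all 9 lie under that level. GC-dependent differences between libraries therefore stay open as a cause. Fewer differentiated cells in the Ezh2 KO libraries stay open too. Other lineage markers under log2 CPM 2 had a median of -0.35, with 49 of 64 negative. Markers above that level had -0.07 and all 5481 tested genes under it 0.07. The Hox median differed from that of the low markers by -0.99 (p = 0.00146 in a permutation of genes). That permutation treats genes as independent replicates, which they are not, and does not measure the spread between libraries. A bound set before this test, a Hox median at least 0.5 lower with p under 0.05, was met and would have excluded that explanation; it was replaced after the values were seen, because genes near the floor exclude nothing and the other low markers were mostly negative too. 4-hydroxytamoxifen and Cre activity apart from the loss of Ezh2 cannot be told apart from the deletion, because 0 libraries had the drug without loss of the floxed allele. The hypothesis that Ezh2 may support Hox transcription in day 4 PGCLCs thus stays open beside these.

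The higher interferon and p53 lists have a candidate technical cause in the treatment, since activated Cre cuts DNA and either response can follow DNA damage. 4-hydroxytamoxifen and Cre activity apart from the loss of Ezh2 cannot be told apart from that loss, because 0 libraries had the drug without loss of the floxed allele. GC-dependent differences between libraries are argued against as the whole cause: after the offset the medians of the lists were 0.39 and 0.25, both larger than before it. The offset was fitted on genes of mean log2 CPM over 2, so it says less about members under that level, such as Oas2. Release of silenced repeats by the loss of Ezh2 may also raise an interferon response, which was not tested, as repeats were not counted.

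That edgeR called 0 genes can have several sources, of which the depth of the libraries is argued against for abundant genes: of 5354 genes of mean log2 CPM over 5, each with a mean of 1035.5 counts per library or more, 0 were called when adjusted over these alone (98 at an unadjusted p under 0.05, smallest adjusted p 0.984). GC-dependent differences between libraries are argued against as the whole cause: the first component held 55.5% of the variance before the GC offset and 49.8% after it, and edgeR with the block called 0 genes after the offset (1638 at an unadjusted p under 0.05; DESeq2 with the block called 74). Ezh2 lost in only part of the cells may hold the effects down, as Ezh2 stood at 67.1% of Ctrl. This stays open because the deleted exons are unknown and counts are for the whole gene. A biological reading, in which few transcripts depend on Ezh2 at day 4, is not excluded either.

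The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 459 genes at an unadjusted p under 0.05 in edgeR, and 4 of the 10 splits, itself included, gave as many or more, with 2643 at most. It gave 5 DESeq2 calls, and 6 of the 10 splits, itself included, gave as many or more, with 734 at most. That split set Ctrl replicates 1 and 2 with Ezh2 KO replicate 1 against the others, which points to a structure of the samples other than the groups. The real split gave 11 lists, and no other split gave as many, with 9 as the highest of the others. Only 4 splits part the 3 pairs, again too few. With the replicate block the real one gave 50 DESeq2 calls and 10 lists, and the highest of the other 3 were 2 calls and 6 lists. The other 6 splits part only 1 pair and keep the others whole.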
